A study of Homo sapiens with 4 samples.

How the data were processed

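CUT&RUN libraries for CTCF in Caki-1, MCF7 and U251 cells and for NRF1 in U251 cells, 1 library per group, were analysed from the peak lists that the authors deposited. Per the series' design text, commercial CUT&RUN and library kits were used, with 500000 cells and 0.5 µg of antibody per reaction, and H3K4me3 and IgG antibodies served as controls; libraries of these controls were not analysed here. Per the submitters' processing notes, FastQC, Picard and MACS2 were used and the genome build was hg38. The aligner, the software versions and the identity of the control given to the peak caller are not given in the sources used here. Chromosome lengths in the files matched hg38.

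Each list holds peaks called by the authors per library, and its column names are those of MACS2. The pileup, a coverage signal in fragments at the summit, was deposited by the authors without a stated depth normalization. The −log10 p and −log10 q values were deposited as the peak caller of the authors gave them, and the lowest −log10 q was 1.00 in every list. The peak names in the files carry the threshold, q = 0.1. The fold enrichment, a ratio of pileup to background, was also deposited as given by the authors' caller. Per the file headers the authors recentred peaks: every peak spans 501 bp around its summit, and no peaks of a list overlap. The lists hold 99.0% of the numbered peaks in Caki-1, 99.3% in MCF7, 99.5% in U251 with CTCF and 97.0% in U251 with NRF1; the filter that removed the rest is not given in the sources used here. Pileups were whole numbers in 3 lists. In the U251 CTCF list they were multiples of 0.572, a scaling whose reason is not given in the sources used here, so its background was divided by that unit where depth is compared.

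The control background at a peak was computed from the deposited values as (pileup + 1) / fold − 1. With it the Poisson upper tail gave back the deposited −log10 p, with a median absolute difference of 1.17e-05 in MCF7 and 0.00262 in U251 with CTCF. The lowest background of a list was used as a guide to depth, since total reads per library were not analysed here; it depends on fragment length as well as on depth. The smallest peaks rested on 4 fragments in Caki-1, MCF7 and U251 with NRF1 and on 7 in U251 with CTCF, so that the height of a single low peak is imprecise. The files hold no separate peak score, so −log10 p took its place to rank and filter peaks, within a list only. Fold and pileup describe single peaks, and q was used for the threshold only. A planned comparison of scores between lists at shared peaks was left out, because scores from lists of different depth are not on 1 scale.

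Peaks of different lists counted as shared when they overlapped by at least 1 bp, which for 501 bp windows was computed from summit distances and checked against bedtools 2.31.1. Shares were given with exact Clopper-Pearson 95% intervals and set beside 100 lists shifted circularly along each chromosome. Transcription starts and gene models came from GENCODE release 44, with 19676 protein-coding genes. A promoter peak had its centre within 1000 bp of a protein-coding start; counts over gene lists used the starts of all members, and random lists stood beside the protein-coding members only. Consensus sequences CCASYAGRKGGCRS for CTCF and YGCGCAYGCGCR for NRF1 were searched on both strands within 100 bp of the centre with at most 1 mismatch, and in windows of the same size 2000 bp to either side. For a count of 0 the upper limit was taken as 3 counts. Pileup intervals are exact Poisson 95% intervals, and all intervals cover counting error only, since fragments without molecular identifiers need not be independent.

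Gene lists were 13 for CTCF (breast luminal, renal, glial, the HOXA, HOXB, HOXC and HOXD clusters, protocadherin alpha, beta and gamma, imprinted, cohesin and CTCF, cancer genes) and 13 for NRF1 (respiratory chain, mitochondrial ribosome, mitochondrial import, mitochondrial DNA maintenance, proteasome, cytosolic ribosome, DNA replication, translation initiation, tRNA synthetases, spliceosome, vacuolar ATPase, germline genes silenced by methylation, olfactory receptors). The number of members with a promoter peak was set beside 10000 random lists of the same size, drawn from all protein-coding genes or matched on the CpG observed/expected ratio of the promoter in 10 bins. These percentiles describe the libraries and are not tests. The lists, the consensus sequences, the rule for named genes and all alternatives but 6 were fixed before the data were examined.

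Genes were named by rule: the 20 highest NRF1 peaks by −log10 p; in each CTCF list the 8 highest peaks absent from both other lists and the 5 highest shared by all 3, by the nearest protein-coding gene; and members of the gene lists with a promoter peak, up to 6 per list and library, with those found in 1 line only. Fewer were named where values were low. With 1 library per group no test between groups was run. Alternatives were other promoter distances, starts of all genes, other mismatch limits, the whole peak as search window, other overlap rules, the higher-scoring part of each list, equal list lengths and autosomes only.

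The code was tested on simulated data. Of 2000 simulated windows, those in which the consensus was placed held it in 100% of cases for both factors, and in windows without it 0.250% held the CTCF and 0.688% the NRF1 consensus by chance. Of 5000 simulated peaks, 30.0% shared at least 1 bp by construction and by both methods. In 20000 simulated genes with a known share of hits, random lists of 100 genes had a median of 10.0 hits. Near-identical copies were sought with blastn 2.17.0 (alignments of at least 300 bp and 85% identity). Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9 were used.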

Results

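CUT&RUN, in which an antibody directs a protein A/G fusion of micrococcal nuclease to cut DNA around its target, was run on 3 established human cancer cell lines with 500000 cells and 0.5 µg of antibody per reaction. CTCF, the zinc-finger protein of insulators and chromatin loop anchors, was profiled in Caki-1 (renal carcinoma), MCF7 (oestrogen receptor positive breast carcinoma) and U251 (glioblastoma) cells. NRF1, nuclear respiratory factor 1, which binds a GC-rich palindrome in promoters, was profiled in U251 cells only. Each of the 4 groups held 1 library, so no difference between groups was tested and every interval below covers counting error within a library only. The lists held 18215 CTCF peaks in Caki-1, 34556 in MCF7 and 9555 in U251, and 577 NRF1 peaks in U251. Read totals were not analysed here. The lowest control-based background at any peak, a guide to coverage, was 0.506 fragments per position in Caki-1, 0.378 in MCF7, 0.466 in U251 with CTCF and 0.184 in U251 with NRF1. The U251 CTCF value was divided by its pileup unit of 0.572. On the scale on which that list was called it was 0.266, below the MCF7 value. MCF7 thus had the longest CTCF list at a lower background than Caki-1, and than U251 only after that division. The NRF1 library had the lowest background of the 4.

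The CTCF lists addressed which binding sites the 3 cell lines shared and which appeared in a single line. A common set of sites was called in all 3 lines: 7025 of the Caki-1 peaks, 7027 of the MCF7 peaks and 7023 of the U251 peaks overlapped a peak in both other lists. These made up 73.5% of the U251 list (exact binomial 95% interval 72.6 to 74.4), 38.6% of the Caki-1 list (37.9 to 39.3) and 20.3% of the MCF7 list (19.9 to 20.8). U251 CTCF peaks were nearly a subset of MCF7 peaks, with 93.2% found there against 75.9% in Caki-1, and 72.8% of Caki-1 peaks were also MCF7 peaks. Peaks found in 1 line alone numbered 19406 in MCF7, 4722 in Caki-1 and 415 in U251. These pairwise shares and counts depend on list length, with MCF7 the longest list and U251 the shortest. They were not computed at equal length, so they do not show which lines are most alike. When both other lists were shifted along the chromosomes at random, the mean three-way share was 0.00587% for Caki-1, 0.00321% for MCF7 and 0.0111% for U251, and no shift of 100 exceeded 0.0419%. With each list limited to its 9555 highest-scoring peaks, 42.1% of peaks in each line were shared by all 3 (41.1 to 43.1), a share that equal lengths make nearly equal between lines by construction.

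**Figure D1:**
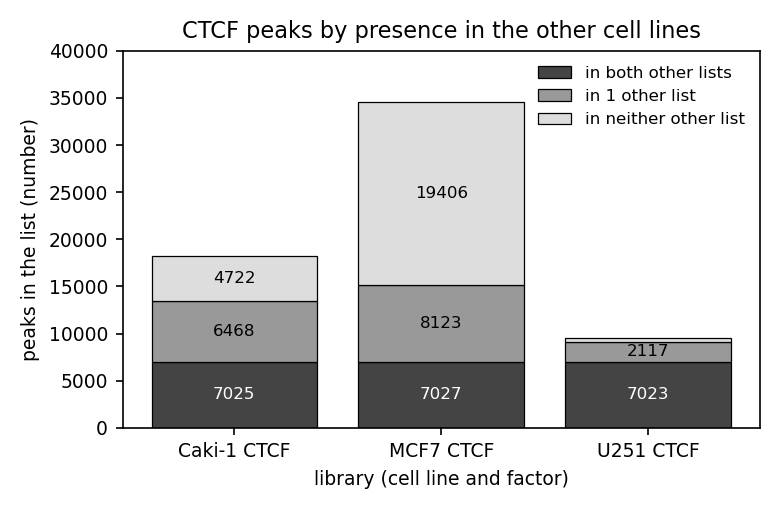
Number of CTCF peaks in each cell line's list (vertical axis), divided by whether the peak overlapped a peak in both other lists, in 1 other list or in neither. The dark segment runs from 7023 to 7027 peaks, while the pale segment runs from 415 peaks in U251 to 19406 in MCF7.

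Shared CTCF sites held the CTCF consensus far more often than sites seen in a single cell line. Among peaks shared by all 3 lines the consensus CCASYAGRKGGCRS, with at most 1 mismatch, lay within 100 bp of the centre in 39.0% of the Caki-1 peaks, 44.2% of the MCF7 peaks and 39.5% of the U251 peaks. Peaks restricted to 1 line had it in 8.94% of cases in Caki-1 (8.14 to 9.79), 21.7% in MCF7 (21.1 to 22.3) and 20.5% in U251 (16.7 to 24.7). Flanking windows 2000 bp away had it in 0.755%, 0.699% and 0.795%, in the same order of lines. Over whole lists the share was 28.8% in Caki-1 (28.1 to 29.5), 30.1% in MCF7 (29.6 to 30.6) and 37.5% in U251 (36.5 to 38.5). This order did not hold at 9555 peaks per list, where MCF7 had 42.1%, Caki-1 38.2% and U251 37.5%. CTCF peaks away from promoters held the consensus more often than promoter peaks, at 32.8% against 13.9% in Caki-1, 35.6% against 10.7% in MCF7 and 42.6% against 19.1% in U251.

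Restricted CTCF peaks were also the weaker peaks of each list by the authors' −log10 p, with medians of 5.45 against 12.6 for shared peaks in Caki-1, 8.61 against 27.3 in MCF7 and 6.48 against 10.2 in U251. In MCF7 the restricted share rose from 18.7% in the first of 5 equal parts of the list by score to 86.7% in the last, and in Caki-1 from 2.53% to 61.4%. The consensus share was also lower in restricted than in shared peaks in every band of like score tabulated for both. In the MCF7 band with −log10 p above 15 and up to 25 it was present in 33.7% of 2848 restricted peaks (32.0 to 35.5) and in 48.1% of 1783 shared peaks (45.7 to 50.4). In the Caki-1 band above 5 and up to 7 the shares were 7.43% of 1641 restricted and 39.1% of 762 shared peaks. The intervals overlapped in the Caki-1 band above 15 and up to 25, with 34.2% of 79 restricted peaks (23.9 to 45.7) and 42.9% of shared peaks (40.6 to 45.3). They also overlapped in the U251 band above 10 and up to 15, with 34.3% of 67 restricted (23.2 to 46.9) and 44% of shared peaks (41.9 to 46.2).

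**Figure D2:**
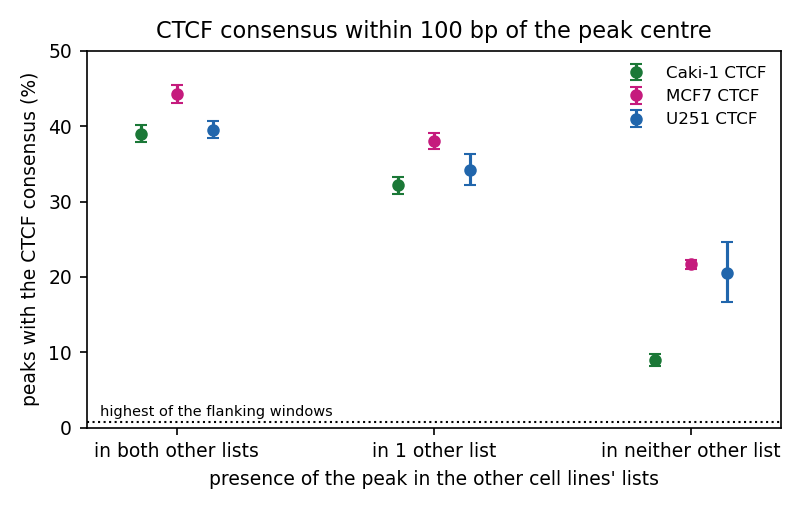
Percent of CTCF peaks with the CTCF consensus within 100 bp of the centre (vertical axis) by presence in the other cell lines' lists (horizontal axis); points are the value in 1 library and bars its exact binomial 95% interval. All 3 lines fall from left to right, and every point lies above the dotted line of flanking windows at 0.795%.

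The strongest CTCF peaks shared by all 3 lines clustered on the long arm of chromosome 15, which held all 5 of the highest in MCF7, 4 of 5 in Caki-1 and 3 of 5 in U251. The highest peak in MCF7 and Caki-1 lay in intergenic sequence 89816 bp upstream of the nearest start of LINGO1 (chromosome 15, 77910466 to 77910966, hg38), with a pileup of 299 fragments (exact Poisson 95% interval 266 to 335) and a fold enrichment of 113 in MCF7. The highest in U251 lay 9660 bp downstream of a start of RPS17, a small-subunit ribosomal protein gene (chromosome 15, 82530547 to 82531047), with a fold of 62.8; the same site ranked second among the shared peaks of both other lists. Other sites among the 5 highest shared peaks lay nearest BBS4, GOLGA6A, GOLGA6D, GOLGA6L4 and ZSCAN2 on chromosome 15. Those nearest ZSCAN2 were 95091 bp from a start in MCF7 and 173908 bp in Caki-1. Further sites lay 121826 bp from the start of LDLRAD3 on chromosome 11 and upstream of NFASC on chromosome 1. Another lay in an untranslated region of EFHD1, 59 bp downstream of a start, on chromosome 2 (fold 68.9 in U251). The 5 highest in MCF7 each had between 22 and 30 near-identical copies elsewhere in the genome, so the assignment of their reads to a copy is uncertain. Fold enrichments, pileups and −log10 p values are those of the authors' peak caller and describe peaks within a list.

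The highest Caki-1 peak with no counterpart in the other lines was at the promoter of EGLN2, a prolyl hydroxylase that marks hypoxia-inducible factor for degradation. It lay 105 bp upstream of the start (chromosome 19, 40806787 to 40807287), with a pileup of 31.0 (21.1 to 44), a fold of 18.5 and a consensus match with 1 mismatch. Next came a coding exon of NR0B1, an orphan nuclear receptor, on chromosome X (30308277 to 30308777, fold 16.1), and an intergenic site 7502 bp upstream of COX6A1, a cytochrome c oxidase subunit (fold 15.5). Promoters of PRKCQ, a T-cell protein kinase C (fold 15.3), and GRIN2B, an NMDA receptor subunit (fold 13.9), and sites nearest NSRP1, FEM1A and ACKR1 completed the 8 highest. The site near FEM1A, 18043 bp from its start, matched the consensus with 0 mismatches.

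Several of the highest MCF7-only peaks lay where the control background was raised. The highest lay in intergenic sequence 27271 bp from the start of CST2, a salivary cystatin (chromosome 20, 23799208 to 23799708), with a pileup of 157 (133 to 184) and a fold of 75.1. It was followed by a site nearest MINAR1 on chromosome 15, 142716 bp from its start (fold 71.8). Next came a site nearest BCAS1, a gene named for its amplification in breast carcinoma, on chromosome 20 (53915558 to 53916058, fold 16.7). An intron of CADPS on chromosome 3 (fold 42.8) came after it. The control background was 15.7 at this BCAS1 site and 19.3 at a second one in its untranslated region, against a list median of 0.749, and it was 2.76 at CADPS and 5.99 near HEATR6 on chromosome 17. Sites near ATP2B2, a plasma membrane calcium pump (fold 57.5), and at the LRFN2 promoter (fold 43.6) had backgrounds of 1.10 and 1.5. The background was also 1.10 at the sites near CST2 and MINAR1. This equals the median of the MCF7 peaks shared by all 3 lines.

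U251-only CTCF peaks numbered 415. The highest was an intergenic site 68893 bp upstream of VOPP1 (chromosome 7, 55641145 to 55641645), with a fold of 13.8, and the next, near RCN1, an endoplasmic reticulum calcium-binding protein, matched the consensus with 0 mismatches (fold 13.0). The remainder of the 8 highest lay nearest GLRX3, LZTS2, DNAI1, PRIM2, PSMB7 and USP17L8, with folds from 9.93 to 12.4. The LZTS2 peak was 321 bp from a start, while the PRIM2 peak lay 2034017 bp from the nearest one. In the CTCF lists similar shares of peaks lay within 1000 bp of a protein-coding transcription start: 21% in Caki-1 (20.4 to 21.6), 21.8% in MCF7 (21.4 to 22.2) and 21.7% in U251 (20.9 to 22.5), against means of 2.75%, 2.71% and 2.91% in shifted lists.

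Genes that mark the tissue of origin of a line did not carry CTCF at the promoter more often there than matched random genes. Of 25 breast luminal genes, 11 had a CTCF promoter peak in MCF7, 7 in Caki-1 and 4 in U251, where the medians of 10000 random lists matched on promoter CpG ratio were 10, 5 and 3. The promoters of ERBB3, a receptor tyrosine kinase, ELF3, an epithelial transcription factor, and FOXA1, a pioneer factor of luminal cells, had a peak in all 3 lines, with a fold of 34.0 at ERBB3 in MCF7 and 20.2 in U251. TFF1 (fold 4.26) and GREB1 (3.63), oestrogen-responsive genes, had one in MCF7 alone, as did TFAP2A, SPDEF and GRHL2, whereas the keratin genes KRT8 (5.0) and KRT19 (3.81) had one in Caki-1 alone. Of 25 renal and hypoxia genes, 2 had a peak in Caki-1, 4 in MCF7 and 1 in U251, with matched medians of 4, 7 and 2. VEGFA, the angiogenic growth factor, had it in all 3 (fold 10.5 in Caki-1, 31.6 in MCF7 and 12.3 in U251), while EPAS1 and ANGPTL4 had it in MCF7 alone. Of 25 glial genes, 1 had a peak in U251, the intermediate filament gene NES, which had it in all 3 lines, against 4 in Caki-1 and 5 in MCF7. The matched medians were 3 in U251, 5 in Caki-1 and 10 in MCF7, where 2.77% of matched lists had as few or fewer. The transcription factor gene SOX2 had it in Caki-1 alone and GFAP and ID1 in MCF7 alone. The MCF7 counts fell to 3 breast luminal, 1 renal and 0 glial genes among its 9555 highest peaks.

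At the protocadherin beta and alpha clusters, MCF7 had more promoters with a CTCF peak than the other lines. CTCF is known to bind alternative protocadherin promoters. The CTCF consensus lay in 1 of 16 MCF7 peaks within the beta cluster, 2 of 8 within alpha and 0 of 9 within gamma. All MCF7 promoter peaks had it in 10.7% of cases and the whole MCF7 list in 30.1%. On chromosome 5, 12 of the 16 protocadherin beta genes had a CTCF promoter peak in MCF7, against 0 in Caki-1, which allows a share of up to 18.8%, and 1 in U251. Only 0.01% of random lists matched on CpG ratio had as many as in MCF7. Those lists draw genes from the whole genome, while the beta genes are neighbours in 1 cluster. The percentile can therefore overstate how rare the count is, and it was not computed at matched list size. The highest of these MCF7 peaks by −log10 p were at PCDHB10 (fold 16.6), PCDHB2 (16.0), PCDHB11 (15.5) and PCDHB8 (11.4), and PCDHB2 was the member with a peak in U251 (9.90). Of 15 protocadherin alpha genes, 8 had a peak in MCF7, led by PCDHA8 (fold 21.1) and PCDHA13 (14.8), 2 had one in Caki-1 and 0 in U251. Of 22 protocadherin gamma genes the numbers were 8, 5 and 3. The matched random lists had as many in 48.0% of cases for alpha and 74.4% for gamma in MCF7. At matched list size the alpha genes with a peak numbered 4 in MCF7, 1 in Caki-1 and 0 in U251, and the beta genes 4, 0 and 1. The gamma genes did not share this order there, with 2 in MCF7, 2 in Caki-1 and 3 in U251. These genes are related paralogues, and how reads were shared between them was not tested.

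**Figure D3:**
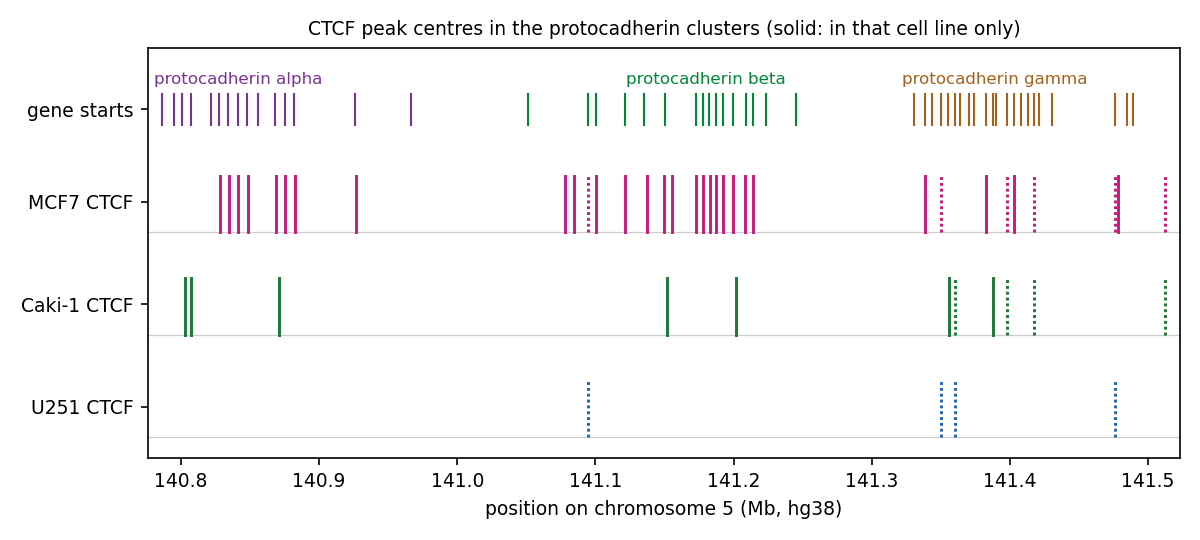
Map of the protocadherin clusters on chromosome 5 (horizontal axis, Mb, hg38) with gene starts in the top row and CTCF peak centres of the 3 cell lines below; solid lines are peaks in that line's list alone and dotted lines peaks with a counterpart in another list. The beta cluster holds 16 peaks in MCF7, 2 in Caki-1 and 1 in U251.

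The HOX clusters had CTCF peaks shared between lines and peaks in 1 line alone. The HOXA cluster (chromosome 7, 27092993 to 27200091) held 6 peaks in Caki-1, 7 in MCF7 and 4 in U251, and each of the 4 U251 peaks was shared by all 3 lines. The highest by −log10 p was centred at 27150868 in MCF7 (fold 33.9), at 27150831 in Caki-1 (15.5) and at 27150850 in U251 (20.3). HOXA10 had a promoter peak in all 3 lines, HOXA5 in Caki-1 and MCF7, and HOXA13 in MCF7 alone. The HOXB cluster held 10, 8 and 6 peaks in Caki-1, MCF7 and U251, the HOXC cluster 4, 6 and 3, and the HOXD cluster 6, 6 and 2. Peaks in 1 line alone made up 1 of the 7 HOXA peaks in MCF7, 2 of the 10 HOXB peaks in Caki-1, 3 of the 6 HOXC peaks in MCF7 and 1 of the 3 in U251, and 2 of the 6 HOXD peaks in both Caki-1 and MCF7. At matched list size HOXA held 6 peaks in Caki-1, 3 in MCF7 and 4 in U251, HOXB 8, 7 and 6, HOXC 4, 1 and 3, and HOXD 3, 3 and 2, so that MCF7 no longer had the most in HOXA and HOXC. Peaks at the HOXC5 promoter were present in all 3 lines. A peak centred at 176140775 in the HOXD cluster had a fold of 30 in MCF7, 20 in Caki-1 and 13.0 in U251.

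Among 28 imprinted genes, 7 had a CTCF promoter peak in Caki-1, 9 in MCF7 and 2 in U251. The 25 protein-coding ones accounted for 6, 8 and 1, and the medians of matched random lists were 6, 11 and 3. At matched list size 4 of the 28 had a peak in Caki-1, 3 in MCF7 and 2 in U251. H19, the non-coding RNA beside the IGF2 control region, had it in all 3 lines with folds from 4.40 in U251 to 6.53 in MCF7. The interval spanning IGF2 and H19 (chromosome 11, 1995166 to 2158391) held 7 peaks in Caki-1, 6 in MCF7 and 3 in U251, and at matched list size 5, 1 and 3. The strongest, centred at 2151773 in MCF7, had folds of 28.0 in MCF7, 18.1 in Caki-1 and 12.9 in U251. PEG10 with SGCE, at 1 shared promoter, had a peak in Caki-1 alone, and GRB10, PHLDA2 and PLAGL1 in MCF7 alone.

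Genes of cohesin and CTCF itself were bound at the promoter more often than most random lists. In each line CTCF, STAG1, STAG2, PDS5A and PDS5B had a promoter peak, and in Caki-1 and U251 these 5 were the only ones of the 11 genes with one. In MCF7 10 of 11 had one, with NIPBL, MAU2, SMC1A, WAPL and RAD21 added, but at matched list size 3 had one in MCF7 against 5 in Caki-1 and 5 in U251. Of matched random lists, 0.770% had as many in MCF7, 1.62% in U251 and 13.1% in Caki-1. The peak at the CTCF gene's own promoter had the highest −log10 p of this list in every line, with a fold of 17.4 in Caki-1, 14.4 in MCF7 and 17.4 in U251. Of 22 cancer genes, 16 had a promoter peak in MCF7, 6 in Caki-1 and 2 in U251, and as many were found in 1.43%, 47.7% and 83.2% of matched lists. TP53 and PIK3CA had it in all 3 lines, ERBB2, MYC, CDK4 and RPS6KB1 in Caki-1 and MCF7, and ZNF217, MET, CDKN2B and CCND1 were among those in MCF7 alone. At ZNF217 and RPS6KB1 the MCF7 pileups were 157 and 210 fragments at folds of only 3.73 and 3.04. At matched list size 3 of the 22 remained in MCF7, 2 in Caki-1 and 2 in U251.

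NRF1 peaks in U251 lay at promoters and within genes far more than CTCF peaks did. Of 577 NRF1 peaks, 274 were within 1000 bp of a protein-coding start, or 47.5% (43.3 to 51.7), and the mean of shifted lists was 4.39%. A further 26.9% lay in introns and 7.97% in exons. Counting promoter peaks that lay within a gene as well, 69.7% had their centre inside a protein-coding gene (65.7 to 73.4), against 47.4% of U251 CTCF peaks (46.4 to 48.4). Intergenic NRF1 peaks made up 17.7% (14.7 to 21), against 44.1% for CTCF in the same cells (43.1 to 45.1). NRF1 peaks were GC-rich, with a median GC content of 59.3% against 53.1% for U251 CTCF. Their enrichment was low: the median pileup was 7 fragments and the median fold 5.15.

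**Figure D4:**
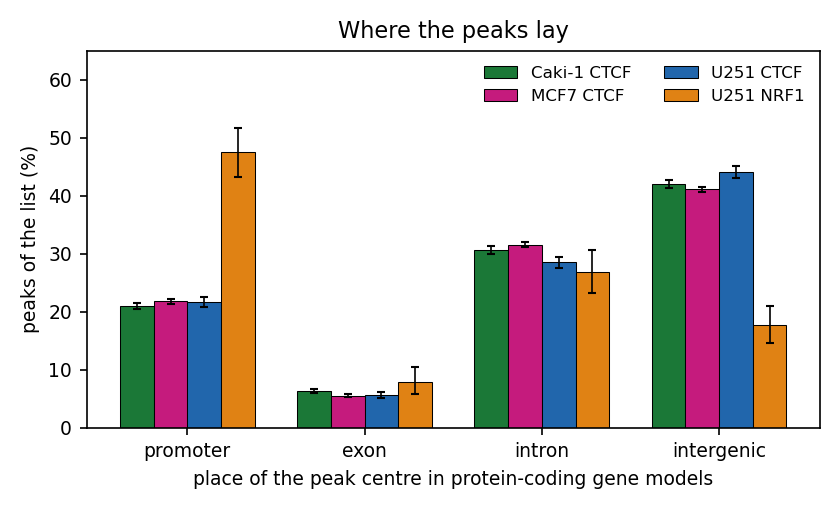
Percent of each list's peaks (vertical axis) with the centre at a promoter, in an exon, in an intron or between protein-coding genes (horizontal axis); bars are 1 library each and error bars exact binomial 95% intervals. NRF1 peaks in U251 are at promoters in 47.5% of cases and the 3 CTCF lists in 21% to 21.8%.

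The NRF1 consensus was rare in the NRF1 peaks. The sequence YGCGCAYGCGCR, with at most 1 mismatch, lay within 100 bp of the centre in 12 of 577 peaks, or 2.08% (1.08 to 3.6), while flanking windows had it in 0.0867% (0.00219 to 0.482). The U251 CTCF peaks had the NRF1 consensus in 1.73% (1.48 to 2.01), and the intervals overlapped. Among promoter peaks the share was 3.65% for NRF1 (1.76 to 6.61) and 5.55% for CTCF in U251 (4.60 to 6.62). Per gene, 66 of 319 genes with an NRF1 promoter peak had the consensus within 250 bp of a start, or 20.7% (16.4 to 25.6), against 18.8% of genes with a U251 CTCF promoter peak (17.2 to 20.5) and 13.4% of all 19676 protein-coding genes (12.9 to 13.9).

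NRF1 promoter peaks were present at 319 protein-coding genes, or 1.62%, and at 0 to 3 members of each of the 13 gene lists fixed for NRF1. The 319 include genes of the mitochondrial chromosome, among them MT-ND4, MT-ND4L, MT-ND3, MT-CO3, MT-ATP6 and MT-ATP8. Shares over these 319 genes were not computed without them. Of 88 respiratory chain genes 3 had one: NDUFS2 (fold 5.45) and NDUFA11 (4.47), of complex I, and COX8A (4.56), of cytochrome c oxidase. Of 78 mitochondrial ribosome genes 3 had one: MRPS34 (5.51), MRPL24 (4.79) and MRPL12 (4.51). These shares were 3.41% (0.709 to 9.64) and 3.85% (0.8 to 10.8), and random lists matched on CpG ratio, with a median of 1 for both, had as many in 21.6% and 20.1% of cases. LONP1 (5.94), the matrix protease, and POLG2 (5.07), the accessory subunit of the mitochondrial DNA polymerase, were the 2 of 18 mitochondrial DNA maintenance genes with a peak, or 11.1% (1.38 to 34.7), as many as in 5.08% of matched lists, whose median was 0. RPS2, RPL36 and RPL13 were the 3 of 83 cytosolic ribosome genes, MCM7 and CDC45 the 2 of 42 DNA replication genes, SRSF7, SNRPA and SRSF2 the 3 of 48 spliceosome genes, and EIF4G1 (7.92) the 1 of 56 translation initiation genes. As many were found in 27.0%, 23.1%, 9.03% and 71.6% of matched lists, with medians of 2, 1, 1 and 1. No peak was found at the 39 proteasome genes, the 25 mitochondrial import genes, the 32 tRNA synthetase genes or the 23 vacuolar ATPase genes, counts of 0 that allow shares of up to 7.69%, 12%, 9.38% and 13.0%. The 17 germline genes silenced by methylation and the 390 olfactory receptor genes also had 0, which allows up to 17.6% and 0.769%.

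The highest NRF1 peaks lay at promoters, in gene bodies and in sequence of high control background. The strongest at a nuclear protein-coding start lay in an intron of USP5, a deubiquitinase gene, 191 bp downstream of a start (chromosome 12, 6852094 to 6852594), with a pileup of 13.0 (6.92 to 22.2) and a fold of 11.8. Others within 1000 bp of a start were at ACTB, the beta-actin gene (chromosome 7, 5527690 to 5528190, fold 9.53, in an untranslated region), IMMT, a mitochondrial inner membrane organiser (9.88), RSPRY1 with PSME3IP1 (9.29), TXNRD2, the mitochondrial thioredoxin reductase (9.37), XRCC3 with ZFYVE21 (9.28), LRRC45 with CENPX (9.24) and ATP8B3 (9.01). Beyond promoters, high peaks lay near ARHGDIA (10.3), GAPDH (10.1), ACTB (9.51) and GRAP (9.90), and inside CCDC200 (7.09), RPTOR (9.35), PNKP with AKT1S1 (9.32) and SAP30BP (9.12). Of the 20 highest NRF1 peaks, those on chromosome 1 at 634029 and 143195200 and on the mitochondrial chromosome at 10674 and 9291 had pileups from 182 to 322 at folds of only 1.85 to 3.14, with a control background of 57.2 to 173 fragments. None of the 20 matched the consensus with at most 1 mismatch.

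U251 was the line profiled for both factors, which allowed NRF1 and CTCF to be set side by side. Of 577 NRF1 peaks, 66 overlapped a U251 CTCF peak, or 11.4% (8.96 to 14.3), and shifted CTCF lists gave a mean of 0.497% and a highest value of 1.56%. Shifting took the CTCF peaks off promoters, from 21.7% to a mean of 2.91%, and 47.5% of NRF1 peaks were at promoters. A shared preference for promoters alone would therefore give an excess over shifted lists, and no promoter-matched overlap was computed. The longer CTCF lists of other cell lines covered more of them, 15.8% with Caki-1 (12.9 to 19) and 28.6% with MCF7 (24.9 to 32.5). At the gene level, 71 of 319 genes with an NRF1 promoter peak also had a U251 CTCF promoter peak, or 22.3% (17.8 to 27.2), against 11.1% of the 19357 genes without one (10.6 to 11.5). The excess was not particular to U251, with 34.2% against 19.5% for the Caki-1 list and 60.8% against 37.6% for MCF7. These shares were not matched on promoter CpG ratio. The NRF1 peaks themselves rarely held the CTCF consensus, in 2.43% of cases (1.33 to 4.04) against 37.5% of U251 CTCF peaks. USP5 and LRRC45 were among the high NRF1 promoter peaks that overlapped CTCF in 2 lines, and ATP8B3 in all 3.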

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

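The mitochondrial chromosome was examined only after the data were seen, and no explanation for it was tested. No comparison set it apart. More than 3 peaks served only to flag it, which is not a test. The CTCF lists held 0 peaks there and the NRF1 list held 5. Their pileups ran from 197 to 322 fragments and their folds from 1.44 to 2.06, on a control background of 128 to 193. The highest by −log10 p lay in a coding exon of MT-ND4L at 10674, and none matched the NRF1 consensus with fewer than 3 mismatches. All 5 are counted in the shares of the NRF1 list, where promoter peaks numbered 274 with them and 270 without. The highest NRF1 peak of the list, at 634029 on chromosome 1, lay in MTATP6P1, a nuclear pseudogene of a mitochondrial gene.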

How the results depend on the processing

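The removal of chrM and high-pileup NRF1 peaks and of bins with raised control background was chosen after the data were seen; all other alternatives were planned. A share counts as moved when it left the exact 95% interval of the reported one, and a number of peaks when it changed by more than 1.5 times. Promoter shares were 17.7% in Caki-1, 18.8% in MCF7, 18.5% in U251 with CTCF and 38.0% for NRF1 within 500 bp of a start, 26.7%, 27.4%, 27.8% and 60.5% within 2500 bp, and 28.2%, 28.2%, 28.9% and 54.1% with the starts of all genes, as narrower or wider definitions give. In the higher-scoring 50% of the lists Caki-1 had 19.7% and MCF7 18.1%, and at equal list lengths also 19.7% and 18.1%; the cause was not tested. NRF1 exceeded each CTCF list under every promoter setting run for both. With 0 mismatches the consensus share was 8.73% in Caki-1, 8.24% in MCF7, 12.4% in U251 with CTCF and 0.347% for NRF1, with 2 it was 49.5%, 54.1%, 59.4% and 6.93%, and over the whole peak 41.7%, 37.7%, 54.7% and 5.2%, as looser searches give. In the higher-scoring 50% the CTCF lists had 38.7%, 39.9% and 39.6%, and at equal lengths Caki-1 had 38.2% and MCF7 42.1%, so the order of the lines depended on the setting; the cause was not tested. The share of peaks found in both other lines was 37.1% in Caki-1, 19.6% in MCF7 and 70.9% in U251 when overlaps had to cover 0.5 of each peak, and 26.2%, 13.9% and 50.4% with centres within 100 bp, since these rules accept fewer overlaps. It was 35.6%, 18.7% and 67.7% among the higher-scoring 50%, for which the cause was not tested, and 42.1% in each line at equal lengths, which make it nearly equal by construction. NRF1 peaks overlapped CTCF in 8.84% of cases with the 0.5 rule, 5.2% with centres within 100 bp, 8.65% among the higher-scoring 50%, and 15.8% and 28.6% with the longer Caki-1 and MCF7 lists. In all 50 such values moved and 14 did not, among these the sharing on autosomes only and both removals named above. Of the other results, 7 moved and 34 did not: the 4 list lengths at 50%, and in MCF7 at equal lengths breast luminal (12%), renal (4%) and glial genes (0). Among the unmoved, U251 at its own length and the shares set beside CpG-matched lists could not move, so they show no stability. Equal length was not run for NRF1, whose list is shorter than any CTCF list. No paired analysis was possible because each group held 1 library. The NRF1 peaks had a median pileup of 7 fragments, which limits the precision of single peaks; whether depth or enrichment set the length of that list was not tested.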

Other observations

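The tests of chance peaks, of extra copies at the 50 highest MCF7-only peaks, of weaker calling and of piled reads below were chosen after the results were seen. CTCF promoter peaks also fell in gene lists fixed for NRF1; of 13 lists in 3 lines, those given here were picked after their values were seen. In U251 cells 23 of 83 cytosolic ribosome genes had a CTCF promoter peak, where matched random lists had a median of 12, and 0.170% of them had as many; in MCF7 46 had one (15.4% of lists) and in Caki-1 27 (8.15%). Of 32 tRNA synthetase genes 11 had a CTCF promoter peak in U251 (0.270% of lists), 10 in Caki-1 (21.7%) and 19 in MCF7 (9.41%). Spliceosome genes had one in 34 of 48 cases in MCF7 (0.210% of lists), 18 in Caki-1 (4.31%) and 13 in U251 (1.74%). Mitochondrial DNA maintenance genes had one in 10 of 18 cases in Caki-1 (0.310%), while 11 in MCF7 (17.3%) and 4 in U251 (23.2%) were matched by more of the lists. Germline genes silenced by methylation went the other way, with 1 of 17 in MCF7 and 0 in Caki-1 and U251, as few as in 0.0800% of lists in MCF7, 1.51% in Caki-1 and 10.8% in U251. Olfactory receptor genes had 5 of 390 in Caki-1, 5 in MCF7 and 1 in U251, where medians of matched lists were 15, 28 and 8.

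NRF1 peaks were unevenly spread over chromosomes: chromosome 19 held 15.8% of them and 7.28% of protein-coding starts, and chromosome 17 held 14.6% and 6.43%, while chromosome 2 held 1.91% and 6.62%, chromosome 18 0.173% and 1.71%, and chromosome 20 1.04% and 2.37%. Some genes held several, with 5 each within MYH9, the non-muscle myosin heavy chain, and CIRBP, an RNA-binding protein, and 4 each within EEF2, the translation elongation factor, FLNA, filamin A, PLEC, plectin, SRF, TNS3, NCOR2, MIDN and SAP30BP. These chromosomes and genes were chosen after their values were seen.

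NRF1 peaks in U251 rarely held the NRF1 consensus. Chance peaks spread over the genome by low depth cannot be the whole cause, since 47.5% lay at promoters against a highest of 7.11% in 100 shifted lists. A consensus too strict to find NRF1 sites would leave an excess at 2 mismatches. Promoter NRF1 peaks then had it in 12.4% of cases (8.75 to 16.9), below the upper bound of 19.6% for promoter CTCF peaks in U251. No excess was thus seen, but the CTCF peaks were not matched on position. Of promoter CTCF peaks 1417 lay upstream of the start and 655 downstream, against 131 and 143 for NRF1. This comparison therefore cannot exclude a consensus that is too strict. Cutting at open promoters rather than at NRF1 sites may account for the rarity at promoters: 53.1% of 1000 sets of promoter points matched on distance to the start and CpG ratio held the consensus at least as often as the 270 nuclear promoter peaks, of which 10 had it. Whether the matched promoters were open was not measured, and binding of NRF1 without its consensus was not tested and stays open.

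In MCF7 19406 CTCF peaks appeared in no other line. Extra copies that bring a 5 Mb bin to at least 2 times the list's median control background do not account for most of them. Of the 19356 below the 50 highest, 5.29% (4.97 to 5.61) lay in the 14 such bins, against 4.57% of peaks shared by all 3 lines. Smaller gains in copy number would not reach that limit, so they stay open. For the 50 highest, extra copies of any size stay open. Of these 50, 21 lay in such bins, but their median background of 1.21 was close to the 1.10 of peaks shared by all 3 lines. It was 1.99 times that of the other restricted peaks. Weaker calling in the other lists stays open too: without those 50 the restricted share was 4.79 times higher in the lowest-scoring than in the highest-scoring of 5 equal parts of the list, but this restates the gradient already seen and decides nothing. Binding that differs between the cell lines was not tested and also stays open.

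The highest shared CTCF peaks lay in duplicated sequence more often than others: 12 of the 50 highest in MCF7 had 5 or more near-identical copies elsewhere, or 24.0% (13.1 to 38.2), against 1 of 200 random shared peaks, and 9 of the 12 lay on chromosome 15. Reads of several copies piled on 1 copy would raise the control there as well. The median control was 1.99 times the list median (bootstrap 95% interval 1.51 to 3.56), under the factor of 5 set for that explanation. Each of the 12 lay above the list median of 0.749, from 1.47 to 16.2 times, the last near SULT2A1. MCF7 peaks shared with both other lines had a median control of 1.10, however, which is also above the list median. The lowest of the 12 had 1.10 as well, and the others lay above it, up to 12.1 near SULT2A1. A value above the list median alone therefore does not point to piling. Piling below the factor of 5 was not tested, so it is not excluded. A family of bound copies, each called, may account for the pattern, since 85.7% of 49 other copies (72.8 to 94.1) had an MCF7 CTCF peak within 500 bp, and 51% had one in Caki-1 and in U251. Reads placed at random among copies would also give a peak at each, so it stays open how many copies are bound. The aligner's handling of such reads is not given in the sources used here, and beyond the family of copies no biological explanation was tested.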
